A study of Arabidopsis thaliana with 56 samples.

How the data were processed

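RNA from leaves of Arabidopsis thaliana was measured on 56 Affymetrix ATH1 arrays, 4 in each of 14 groups. The groups were the accession Col-0 and the mutant eds16-1, each sampled uninfected at 0 h, infected with the powdery mildew Golovinomyces orontii at 6 h and at days 1, 3, 5 and 7, and uninfected at day 7. Per the labels, the 4 replicates came from 3 independent experiments, one of which gave an extra replicate, and which number belonged to which experiment was not given in the sources used here. The labels also say that infected plants stood in a growth chamber of their own, that both genotypes alternated within each box, and that the 6 h time point was infected at another hour than the other times.

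The values deposited by the authors were log2 expression values, made with RMA in the affy package per the submitters' processing notes, without detection calls. The table held 22810 probe sets with values from 2.85 to 13.98. Array medians lay between 5.75 and 5.88 and interquartile ranges between 2.97 and 3.57. Correlations between arrays ran from 0.908 to 0.996, and there were 0 identical pairs. Signal over background was not given, so the number of arrays limits the precision stated here.

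After 64 control probe sets were left out, probe sets were joined to genes by the annotation that came with the array, and 13286 genes matched a gene table by identifier. The table used here named 1 gene for 13513 probe sets and several genes for 503, and 8730 probe sets had no name in it. Where a gene had several probe sets, the one with the highest mean over all arrays stood for it, which set aside 157. The 22589 features tested thus comprised 13356 named genes, of which 1535 had a symbol and 11821 a locus name alone, the 8730 unnamed probe sets and the 503 with several genes. No probe set was named as ICS1, the gene mutated in eds16-1, so its own level was not analysed here.

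A model with 1 mean per group was fitted to all 56 arrays with limma 3.58.1 in R 4.3.3, with 42 residual and 3.38 prior degrees of freedom. It gave 24 comparisons: 7 between genotypes, 5 infection responses in each genotype, 5 interactions, and the change of uninfected leaves from 0 h to day 7 in each genotype. The 0 h leaves were the control up to day 5 and the day 7 uninfected leaves at day 7. Positive genotype differences mean a higher value in eds16-1, and a positive interaction means a higher response in eds16-1 than in Col-0. Benjamini-Hochberg adjustment was made within each comparison, and a feature was called at an adjusted p under 0.05. Errors of log2 changes are standard errors from limma, with n = 4 arrays in each group, and levels are given with the SD. The fit takes these arrays as independent. It leaves out the pairing by number reported below and the shared origin of replicates from 1 experiment. Only the alternatives with a replicate block allow for the pairing.

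Genes were named by a rule: among called named genes whose values in the groups compared did not overlap, the 10 with the largest change in each direction for both responses at day 7, the genotype difference at day 7 and the interactions at days 5 and 7, and the 3 largest elsewhere. Up to 4 members of each gene list were added. Any probe set or gene outside this rule is said to be so. Of 404 members of 27 gene lists, 60 were on the array by name: 11 lists had 3 or more, 11 had 1 or 2, and 5 had none. The other members may be measured by probe sets without a name in the table used here. Counts of list members below cover the named ones only. A further 25 families, of 7 to 69 genes, were formed by symbol after the annotation had been opened and before any comparison was computed. Lists of at least 3 genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the 36 lists within each comparison. Groups, comparisons, lists, the naming rule and the alternatives were fixed before the data were examined, except those families and 2 alternatives.

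Alternatives were median centring, a second quantile normalization, a filter on the dimmest 40% of features, all probe sets, only the groups compared in the fit, a trended and robust prior, a log2 threshold of 1, other uninfected controls, a replicate block, an estimated correlation, and leaving out each array or number in turn. The 2 alternatives chosen after seeing the data were a replicate block within each condition and a reduction of both day 7 uninfected groups to numbers 1 to 3. Whether replicate numbers pair the samples was checked from the correlation of deviations from group means. Of 364 same-number pairs of arrays, 266 correlated above 0.1, with a mean of 0.254 against −0.084 for other numbers, and 52 of 56 arrays lay closest to their own number. The first residual component held 18.9% of the variance and replicate number explained a share of 0.556 of it. In 8 of 19 pairings of groups every pair was above 0.1: the genotype comparisons apart from uninfected day 7, and the day 1 responses of both genotypes. The pairing comes from the data, since the labels do not say what a number stands for. With 4 arrays against 4, the smallest two-sided p of an exact permutation test is 0.0286.

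The calculation was tested on simulated data with 22589 features. For the genotype difference at day 7, 56.7% of features changed 1.5-fold were recovered, 89.6% of those changed 2-fold and 100% of those changed 4-fold, and 5 of 169 calls had no planted change. The response of eds16-1 gave 61.2%, 88.1% and 100%, with 10 of 176 calls unplanted, and the interaction gave 34.3%, 77.6% and 100%, with 10 of 151 unplanted. At most 1 feature was called in any single one of the 21 other comparisons. A list of 30 genes shifted by 0.5 was called, and 0 of 100 unchanged lists were. The simulated features were independent of one another and had no shared replicate effect. These rates therefore do not carry over to lists of correlated genes or to arrays paired by number. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and plots.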

Results

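Transcript levels were measured on 56 arrays of Arabidopsis leaves, 4 arrays in each of 14 groups. Leaves came from Col-0 and from eds16-1, which lacks functional isochorismate synthase 1 (ICS1), an enzyme of salicylic acid synthesis. Both genotypes were sampled uninfected at 0 h, then 6 h (6 hpi) and 1, 3, 5 and 7 days (dpi) after inoculation with powdery mildew, a fungus that feeds from living epidermal cells, and uninfected again at day 7. Values were log2 expression values, and 22589 features were tested, 13356 of them named genes. Array medians differed little, from 5.75 to 5.88. In each comparison the median change of all features lay close to 0, between −0.04 and 0.02. Differences between groups in the 3′ minus 5′ signal of control transcripts, a sign of RNA quality, gave a lowest exact permutation p of 0.229 over 19 comparisons, where 0.0286 is the smallest that 4 against 4 arrays can give, and group means lay between 1.05 and 1.26.

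The response of Col-0 asks which transcripts change as the mildew establishes itself and sporulates. Infected plants stood in a growth chamber of their own, so at every time an effect of that chamber cannot be told apart from infection by design. A check limited to the features called at 6 hpi is given below. The 6 hpi leaves were infected at another hour, and no uninfected leaves of 6 h were analysed here. Whether they were also harvested at another hour than the 0 h leaves is not known here. Their changes from 0 h may thus include those of the hour of the day, which cannot be told apart from infection. At 6 hpi genes of the photosynthetic light reactions fell in Col-0. WRKY53, a defence and senescence transcription factor, rose by 2.23 ± 0.39 (log2 change ± SE, n = 4 arrays in each group, adjusted p = 3.2e-05), and the ubiquitin ligase gene PUB23 rose by 1.97 ± 0.33. LHCB4.2, a light-harvesting antenna protein, fell by 2.43 ± 0.14 (adjusted p = 7.6e-18), from a mean level of 12.88 at 0 h to 10.45. The clock gene GI fell by 2.96 ± 0.21 (adjusted p = 8.3e-15). The largest increases among named genes were those of AT2G23910 (11.1-fold, adjusted p = 8.3e-08), AT3G19030 (7.24-fold) and AT1G06000, a flavonol rhamnosyltransferase (6.96-fold). AT1G73480 fell by 4.17 ± 0.21 (adjusted p = 4.7e-20), AT5G62360, a pectin methylesterase inhibitor, by 3.31 ± 0.58 (adjusted p = 3.6e-05) and the cytochrome P450 gene CYP71B26 by 3.29 ± 0.29 (adjusted p = 2.4e-12).

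All 6 named genes of the light reactions list fell at 6 hpi (list adjusted p = 3.4e-09, and adjusted p = 0.0308 with an estimated correlation), among them PSAN by 1.81 ± 0.28 and PSBW by 0.46 ± 0.09. Of 6 early pattern response genes 5 rose, as many as adjusted over the list alone (list adjusted p = 0.000486, but adjusted p = 0.0859 with an estimated correlation). They included WRKY22, which rose by 0.81 ± 0.14. GRX480, a glutaredoxin that interacts with TGA factors, rose by 1.08 ± 0.25 (adjusted p = 0.00142). It was the only 1 of 22 genes of the salicylic acid response list found by name. AT5G52810, known as SARD4, rose by 0.81 ± 0.23 and the jasmonate methyltransferase gene JMT by 1.22 ± 0.21, each 1 of 2 named members of its list. Among endoplasmic reticulum folding genes 2 of 3 rose, with ATERDJ3B at 1.13 ± 0.20 (list adjusted p = 0.0262, and adjusted p = 0.322 with an estimated correlation). LTI30, of the cold and abscisic acid list, fell and the auxin-responsive IAA29 fell by 1.99 ± 0.43, while the sugar transporter gene SWEET11 rose by 1.02 ± 0.21. In all, 3506 features were called, 1893 higher and 1613 lower, of which 863 changed by at least 1 on the log2 scale. Among all 13356 named genes, called or not, 2010 had values that did not overlap between the groups, where chance gives 2.86%. The probe set 252367_at, outside the rule for named genes and chosen after its value was seen, rose by 5.73 ± 0.66.

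At 1 and 3 dpi the response in Col-0 was 0 calls by limma, with 306 and 766 features at an unadjusted p under 0.05. With the replicate block 1 feature was called at 1 dpi. With the day 7 uninfected leaves as the control in place of the 0 h leaves, 1125 and 7 were called. Without Col-0 3 dpi replicate 1 the count at 3 dpi was 6.

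At 5 dpi the berberine-bridge-like gene AT1G26380 rose 15.3-fold in Col-0 (log2 change 3.93 ± 0.26, n = 4, adjusted p = 1.0e-15), AT1G65690 rose 14.6-fold and the auxin-conjugating enzyme gene GH3.3 rose 11.1-fold. WES1, another enzyme that conjugates auxin, rose by 3.00 ± 0.23 and WRKY53 by 3.23 ± 0.39. All 3 endoplasmic reticulum folding genes rose: the chaperone cofactor gene ATERDJ3B by 1.51 ± 0.20, the calreticulin gene CRT1b by 1.12 ± 0.17 and the stress transcription factor gene BZIP60 by 0.86 ± 0.16 (list adjusted p = 7.0e-05, and adjusted p = 0.0332 with an estimated correlation). Of the 13 genes listed for salicylic acid synthesis and its regulators 2 were found by name, AT5G52810 and SAG101. Both rose (SAG101 by 1.12 ± 0.23), as did GRX480 by 1.57 ± 0.25 and UGT76B1, a glucosyltransferase that acts on salicylic acid, by 0.98 ± 0.22. WRKY6, of the senescence list, rose by 1.33 ± 0.17. The largest decreases were those of AT2G10940 (−2.55 ± 0.81, adjusted p = 0.0219), AT1G09750 (−2.28 ± 0.56, adjusted p = 0.00264) and AT1G13650 (−2.15 ± 0.60, adjusted p = 0.00862).

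Of the early pattern response genes 3 of 6 rose at 5 dpi (list adjusted p = 0.0163, and adjusted p = 0.212 with an estimated correlation), and of the auxin genes 2 of 3 (list adjusted p = 0.000218, and adjusted p = 0.0749 with an estimated correlation). In the light reactions 2 of 6 genes fell, or 4 adjusted over the list alone, PSAN among them (list adjusted p = 0.0177, and adjusted p = 0.337 with an estimated correlation). SBPASE and PRK of the Calvin cycle fell by 0.52 ± 0.11 and 0.22 ± 0.08 (list adjusted p = 0.0406, and adjusted p = 0.337 with an estimated correlation). Both named genes of the aliphatic glucosinolate list fell, AT2G31790 by 0.62 ± 0.19 and BCAT4 by 0.54 ± 0.16, the latter without passing when Col-0 0 h replicate 1 (adjusted p = 0.0696) or 3 (0.0557) was left out. There were 3839 calls, 2074 higher and 1765 lower, 731 of them by at least 1, and 2306 without Col-0 5 dpi replicate 4. Without that array the calls of AT2G10940 (−1.49, adjusted p = 0.257) and AT1G09750 (−1.55, adjusted p = 0.0533) ended. Against the day 7 uninfected leaves both turned, to 1.11 and 0.29, and AT2G31790 was at −0.43 (adjusted p = 0.119), while the call of AT1G13650 ended without Col-0 0 h replicate 1 (−1.49, adjusted p = 0.0996).

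By 7 dpi GH3.3 in Col-0 was 51.9-fold above the uninfected leaves of the same day (log2 change 5.70 ± 0.27, n = 4, adjusted p = 1.3e-21). AT2G44240 rose 43.4-fold, AT3G18250 39.7-fold, and the berberine-bridge-like genes AT1G26390, AT1G26380 and AT1G26410 rose 36.8-fold, 36.3-fold and 19.9-fold. CHI, a chitinase, rose 26.8-fold, the leucine-rich repeat kinase gene AT1G51890 25.8-fold, AT5G38900 25.4-fold and AT1G78410 20.1-fold. Among these 10 genes the highest adjusted p was 3.1e-14, that of CHI. The largest decrease was that of AT5G55620 (−2.83 ± 0.34, adjusted p = 3.3e-09). AT3G21670, a nitrate transporter gene, fell by 2.64 ± 0.50, AT4G12980 by 2.64 ± 0.50, AT3G20820 by 2.52 ± 0.28 and AT5G02230 by 2.43 ± 0.40. Log2 changes of AT1G27030 (−2.27), AT5G45950 (−2.27), a GDSL lipase, AT1G51090 (−2.26), AT3G19850 (−2.22) and AT2G29290 (−2.21) also passed, with the highest adjusted p 4.6e-05.

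WRKY53 rose by 4.15 ± 0.39 at 7 dpi and PUB23 by 2.45 ± 0.33, among 4 of 6 early pattern response genes that rose (list adjusted p = 0.0117, and adjusted p = 0.172 with an estimated correlation). ATERDJ3B rose by 2.23 ± 0.20, CRT1b by 1.70 ± 0.17 and BZIP60 by 0.94 ± 0.16 (list adjusted p = 0.000511, and adjusted p = 0.0792 with an estimated correlation). AT5G52810 rose by 2.54 ± 0.23, SAG101 by 1.49 ± 0.23, GRX480 by 2.84 ± 0.25, UGT76B1 by 2.09 ± 0.22 and WRKY6 by 2.41 ± 0.17. Calcium-binding genes rose in 3 of 4 cases, or 4 adjusted over the list alone, led by CML41 at 1.94 ± 0.24 (list adjusted p = 0.00865, and adjusted p = 0.0792 with an estimated correlation). GH3.3 and WES1, at 3.95 ± 0.23, were the 2 of 3 auxin genes that rose (list adjusted p = 0.000741, and adjusted p = 0.0792 with an estimated correlation). All 3 Calvin cycle genes fell, SBPASE by 1.16 ± 0.11, PRK by 0.60 ± 0.08 and the activase gene RCA by 0.25 ± 0.09, the last without passing when any of 5 of the 8 arrays was left out (list adjusted p = 0.00407, and adjusted p = 0.145 with an estimated correlation). In the light reactions 4 of 6 genes fell, or 5 adjusted over the list alone, with PSAN at −1.21 ± 0.28 and LHCB4.2 at −0.57 ± 0.14 (list adjusted p = 0.0197, and adjusted p = 0.405 with an estimated correlation). COR15A fell by 1.84 ± 0.40 and COR47 by 1.43 ± 0.27, among 3 of 4 cold and abscisic acid genes that fell (list adjusted p = 0.0384, and adjusted p = 0.413 with an estimated correlation). In their control group, uninfected Col-0 of day 7, replicate 4 stood apart for COR47 (12.61, against a mean of 11.31 in the others) and LTI30 (12.25, 9.63), and without it COR47 fell by 1.11.

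At 7 dpi in Col-0 the defensin genes PDF1.2 and PDF1.2b stood at 0.20 (adjusted p = 0.934) and 0.65 (adjusted p = 0.656). Their sign rested on the control: without Col-0 day 7 uninfected replicate 4, where PDF1.2 stood at 4.06 against 7.75, 9.53 and 10.37 in the other arrays, they stood at −1.09 and −0.20, and PDF1.2 also turned without Col-0 7 dpi replicate 1 (−0.15). Further genes that did not pass were the guard cell marker FMA at −0.30 (adjusted p = 0.341), UGT74B1 of the indole glucosinolates at 0.37 (adjusted p = 0.0739), and the redox genes GR1 and GSTU25 at 0.12 and 0.005. Of the 3 reference genes AT4G34270 rose by 0.40 ± 0.08 and PEX4 fell by 0.31 ± 0.10 (adjusted p = 0.0179), the latter call ending without replicate 3 of the 7 dpi (adjusted p = 0.0516) or day 7 uninfected group (0.106), while AT2G28390 stood at −0.03. There were 6741 calls, 3347 higher and 3394 lower, 1641 of them by at least 1. They held 1810 of the 2074 features that were higher at 5 dpi (307.3 expected from independent lists) and 1473 of the 1765 that were lower (265.2 expected). Here and below, expected overlaps take the lists as independent, although many arrays of the same number shared part of their deviations from the group means.

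**Figure D1:**
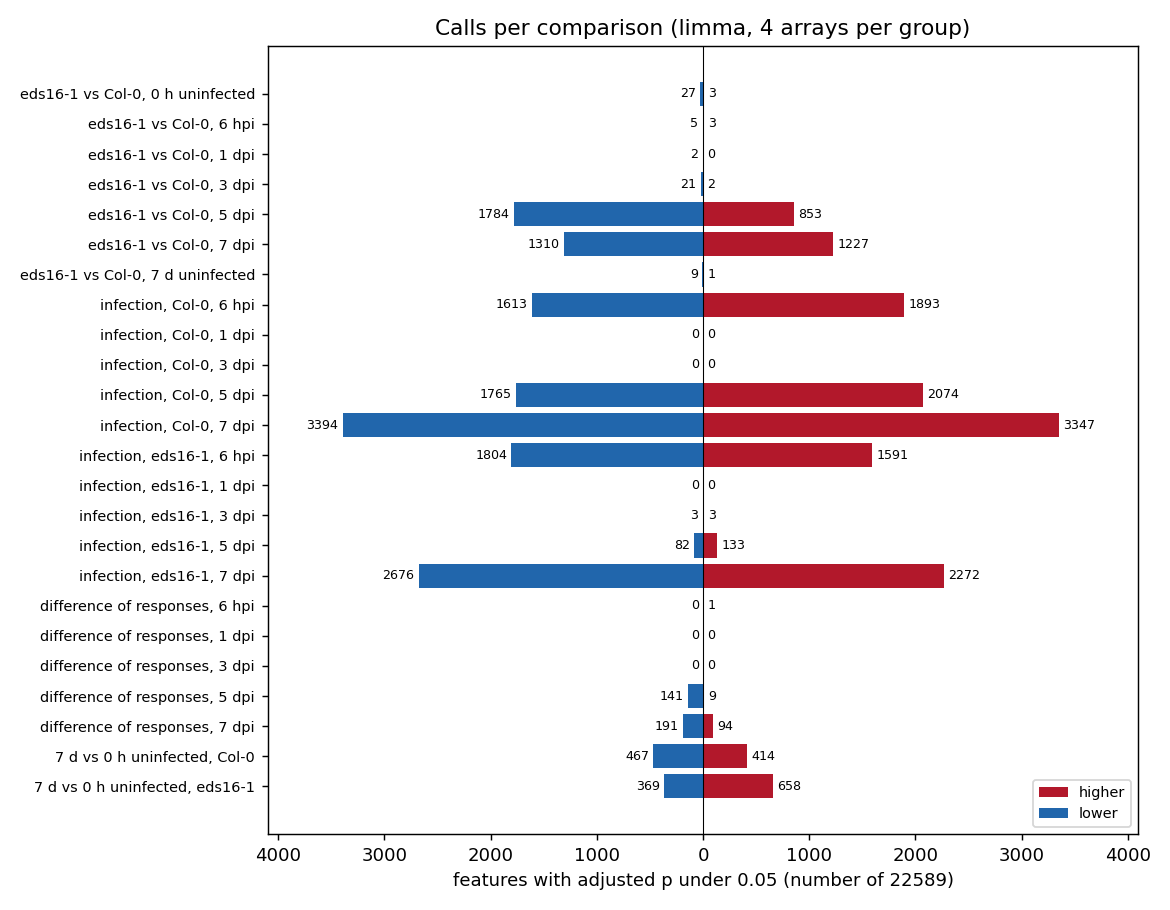
Number of features (x axis, of 22589 tested) with an adjusted p under 0.05 in each of 24 comparisons (y axis), with higher features as red bars to the right and lower ones as blue bars to the left. Directions are eds16-1 minus Col-0, infected minus uninfected, response of eds16-1 minus response of Col-0, and day 7 minus 0 h; the longest bars are those of Col-0 at 7 dpi (3347 and 3394), while Col-0 at 1 and 3 dpi has 0.

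The same responses were followed in eds16-1 to learn which of them arise without ICS1. As in Col-0, infection cannot be told apart from a possible change of hour at 6 hpi, nor from the separate growth chamber at any time. At 6 hpi LHCB4.2 fell by 2.41 ± 0.14 in eds16-1 and GI by 3.08 ± 0.21 (n = 4 arrays in each group, adjusted p = 9.9e-18 and 2.3e-15), while WRKY53 rose by 2.11 ± 0.39, PUB23 by 1.36 ± 0.33 and AT5G52810 by 1.30 ± 0.23. AT2G23910 rose 12.2-fold, AT5G59670 9.95-fold and the mannan synthase-like gene CSLA01 9.65-fold. AT1G73480 fell by 4.07 ± 0.21, AT5G62360 by 3.54 ± 0.58 and AT1G20030 by 3.43 ± 0.20. All 6 genes of the light reactions fell (list adjusted p = 1.1e-08, and adjusted p = 0.0412 with an estimated correlation). Of the early pattern response genes 4 of 6 rose, or 5 adjusted over the list alone (list adjusted p = 0.000537, and adjusted p = 0.0897 with an estimated correlation). GRX480 rose by 0.82 ± 0.25, JMT by 0.79 ± 0.21 and SWEET11 by 0.66 ± 0.21. The anthocyanin gene DFR rose by 2.61 ± 0.75, a call that ended without eds16-1 6 hpi replicate 3 (adjusted p = 0.107), and its list of 3 did not pass (adjusted p = 0.0616). There were 3395 calls, 1591 higher and 1804 lower. Against the day 7 uninfected leaves the count was 5748, and against the mean of both uninfected groups 5205. Of the higher ones 1316 were also higher in Col-0 (133.3 expected) and of the lower ones 1241 were lower (128.8 expected).

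Few calls were made in eds16-1 at 1 and 3 dpi. By limma 0 features were called at 1 dpi, with 367 at an unadjusted p under 0.05, and 6 at 3 dpi, 3 higher and 3 lower. AT5G45670 (−0.73 ± 0.14, n = 4, adjusted p = 0.0217) and AT1G10640 (−0.51 ± 0.10, adjusted p = 0.0358) were the named genes among the 6. Each call ended without any of 7 of the 8 arrays, and against the day 7 uninfected leaves their changes were 0.11 and 0.01. The count of 6 became 0 without eds16-1 0 h replicate 3 or eds16-1 3 dpi replicate 3, 1 without 3 dpi replicate 2, 2 without 3 dpi replicate 1, and 3 without 3 dpi replicate 4 or 0 h replicate 1 or 2. It was 3 with either other uninfected control, 2 with the dimmest features left out and 1 with only these groups in the fit.

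At 5 dpi AT1G26380 rose 9.90-fold in eds16-1 (log2 change 3.31 ± 0.26, n = 4, adjusted p = 1.9e-12), GH3.3 7.07-fold and WES1 6.18-fold. The last pair were 2 of 3 auxin genes (list adjusted p = 9.2e-12, and adjusted p = 0.000306 with an estimated correlation). BGLU47, a beta-glucosidase, fell by 1.35 ± 0.28 (adjusted p = 0.00561, or 0.0628 without eds16-1 5 dpi replicate 1). TBL26 (−1.63 ± 0.38, adjusted p = 0.0164) and AT5G45950 (−1.28 ± 0.32, adjusted p = 0.0308) lost their calls without any of 4 and 6 of the 8 arrays, and against the day 7 uninfected leaves BGLU47, TBL26 and AT5G45950 were at −0.74, −0.60 and −0.17 and did not pass. There were 215 calls, 133 higher and 82 lower, and 99 changed by at least 1. The share of higher calls was 61.9%, or 72.1% after a second quantile normalization. The count was 112, 113 and 130 without eds16-1 0 h replicates 1, 2 and 3, 84 without eds16-1 5 dpi replicate 1, 1634 against the day 7 uninfected leaves, 638 against the mean of both uninfected groups and 447 with the replicate block. All 133 higher features were also higher at 7 dpi (13.4 expected) and 67 of the 82 lower ones were lower (9.71 expected).

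At 7 dpi AT1G26390 rose 50.9-fold in eds16-1 (log2 change 5.67 ± 0.28, n = 4, adjusted p = 7.2e-21), AT1G26380 48.8-fold and GH3.3 45.2-fold. AT3G18250 rose 23.2-fold, CHI 22.2-fold, AT1G51890 21.3-fold, AT4G12490 19.3-fold, AT2G18690 19.2-fold, WES1 18.9-fold and AT5G38900 17.1-fold. The largest decreases were those of AT3G19850 (−2.81 ± 0.43), AT3G20820 (−2.55 ± 0.28), AT1G62510 (−2.52 ± 0.46), AT5G45950 (−2.42 ± 0.32) and AT5G57340 (−2.29 ± 0.32). AT1G54820, AT4G34220, AT5G11420, the xyloglucan endotransglucosylase gene XTH32 and AT3G21670 changed by −2.22, −2.18, −2.16, −2.15 and −2.14, with the highest adjusted p 0.00104.

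All 3 endoplasmic reticulum folding genes rose in eds16-1 at 7 dpi, ATERDJ3B by 1.08 ± 0.20, CRT1b by 0.99 ± 0.17 and BZIP60 by 1.01 ± 0.16 (list adjusted p = 0.00121, and adjusted p = 0.0531 with an estimated correlation). PUB23 rose by 2.58 ± 0.33 and WRKY53 by 2.22 ± 0.39, which made 2 of 6 early pattern response genes (list adjusted p = 0.0300, and adjusted p = 0.365 with an estimated correlation). All 4 calcium-binding genes rose, CML41 by 1.48 ± 0.24 and CML37 by 0.76 ± 0.12 (list adjusted p = 0.00342, and adjusted p = 0.0531 with an estimated correlation), although CML38 and CML42 lost their calls without any of 5 and 4 of the 8 arrays. GH3.3 and WES1 made 2 of 3 auxin genes (list adjusted p = 1.5e-05, and adjusted p = 0.0519 with an estimated correlation). WRKY6 rose by 2.37 ± 0.17, SAG101 by 1.32 ± 0.23 and AT5G52810 by 1.28 ± 0.23. GRX480 and UGT76B1 stood at 0.05 (adjusted p = 0.931) and 0.01 (adjusted p = 0.981). Of the light reaction genes 5 of 6 fell, LHCB4.2 by 0.61 ± 0.14 and PSAE-1 by 0.30 ± 0.08 (list adjusted p = 0.0107, and adjusted p = 0.413 with an estimated correlation), although LHCB4.1 and PSBY lost their calls without any of 6 and 4 of the 8 arrays. SBPASE fell by 0.49 ± 0.11 and COR47 by 1.09 ± 0.27. SIM, the 1 named gene of the cell cycle and endoreduplication list, fell by 0.68 ± 0.19 (adjusted p = 0.00768, or 0.094 without eds16-1 7 dpi replicate 3).

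Both defensin genes rose in eds16-1 at 7 dpi, PDF1.2 by 3.21 ± 1.05 (adjusted p = 0.0219) and PDF1.2b by 2.43 ± 0.82 (adjusted p = 0.0259). These calls rested on the control: without eds16-1 day 7 uninfected replicate 4, where PDF1.2 stood at 4.06 against 9.70, 11.73 and 10.84 in the other arrays, the changes were 1.54 and 1.24 (adjusted p = 0.295 for each). PDF1.2 also lost its call without eds16-1 7 dpi replicate 2 (adjusted p = 0.052) or 3 (0.0624), and PDF1.2b without 7 dpi replicate 1 (0.055), 2 (0.0605) or 3 (0.0652). There were 4948 calls at 7 dpi, 2272 higher and 2676 lower, 1057 of them by at least 1. Of the higher ones 1882 were higher in Col-0 too (336.6 expected) and 4 lower, and of the lower ones 2147 were lower in Col-0 (402.1 expected) and 3 higher.

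The genotype differences ask which transcripts depend on ICS1 at each time, infected or not. Before infection AT1G13470 was 7.12-fold lower in eds16-1 than in Col-0 (log2 difference −2.83 ± 0.57, n = 4, adjusted p = 0.0305), AT5G52750 4.11-fold and the cytochrome P450 gene CYP71B23 3.60-fold lower (adjusted p = 0.0351). AT5G47330 was 1.94-fold and AT4G22250 1.54-fold higher. Of 22589 features 30 were called, 3 higher and 27 lower. A replicate block within each condition raised this count, as given below. At 7 dpi 25 of the 27 were again lower (1.57 expected), and at 3 dpi 12 were (0.0251 expected). Each of the 5 gene calls ended without any of 5 to 8 of the 8 arrays, and the count fell to 1 without Col-0 replicate 2, 3 or 4 or eds16-1 replicate 2 or 3, and to 2 without eds16-1 replicate 1.

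At 6 hpi CSLA01 was 4.37-fold higher in eds16-1 (2.13 ± 0.29, n = 4, adjusted p = 2.1e-05), with mean levels of 8.92 and 6.79 in the 2 genotypes. AT1G23205 was 2.93-fold higher (adjusted p = 6.3e-06), AT3G61920 1.73-fold higher (adjusted p = 1.3e-05), and AT3G53310 was lower by −0.90 ± 0.18 (adjusted p = 0.0425), which ended without any of 5 of the 8 arrays. With only the arrays of 6 hpi in the fit none of the 4 passed (CSLA01 adjusted p = 0.0715), and the count of 8 features, 3 of them higher (37.5%, or 75% after median centring and 60% after a second quantile normalization), became 0. It was 14 with the replicate block, 4 without Col-0 replicate 3 or eds16-1 replicate 4, 5 without eds16-1 replicate 2, 20 without Col-0 replicate 2 and 21 without eds16-1 replicate 1.

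At 1 dpi 2 features were lower in eds16-1, neither with a name in the table used here. One of them, 262177_at, which lies outside the rule for named genes and was chosen after its value was seen, differed by −1.52 ± 0.25 (n = 4, adjusted p = 0.00413). The count was 1 with only the arrays of 1 dpi in the fit, 1 without Col-0 replicate 2 or 4 or eds16-1 replicate 1, and 0 without Col-0 replicate 3. At 3 dpi AT3G28540 (−1.68 ± 0.37, adjusted p = 0.0489), the starch-related gene QQS (−1.62 ± 0.36, adjusted p = 0.0489), AT2G30695 (−1.55 ± 0.32, adjusted p = 0.0335) and AT5G52810 (−1.15 ± 0.23, adjusted p = 0.0335) were lower in eds16-1, and AT4G22250 was higher by 0.58 ± 0.12. There were 23 calls, 21 of them lower, 35 with the replicate block and 1 with only the arrays of 3 dpi in the fit. The calls of AT3G28540, QQS, AT2G30695 and AT4G22250 each ended without any of 6 or 7 of the 8 arrays. The count was 278 without Col-0 replicate 1, 1 without Col-0 replicate 2, 3 without replicate 3 and 2 without replicate 4, and without eds16-1 replicates 1, 2, 3 and 4 it was 11, 4, 8 and 1.

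At 5 dpi the lectin gene AT5G03350 was 27.0-fold lower in eds16-1 than in Col-0 (−4.75 ± 0.78, n = 4, adjusted p = 1.6e-05), with mean levels of 7.59 ± 0.63 and 12.35 ± 0.16 (SD). Its values were lower in eds16-1 at 0 h already, from 7.73 to 10.29 against 10.36 to 12.06 in Col-0, so part of this difference preceded infection. AT3G48080, a near-identical copy of the immunity gene EDS1, was 12.3-fold lower (adjusted p = 9.5e-07) and WRKY53 10.2-fold lower (adjusted p = 2.1e-08). AT2G43550, a defensin-like gene, was 3.32-fold higher (adjusted p = 0.00476). AT5G13140 and AT5G01015 were higher by 1.55 ± 0.44 and 1.46 ± 0.39, calls that ended without Col-0 replicate 4 (1.16 and 1.23, adjusted p = 0.133 and 0.0618) and, for AT5G01015, without eds16-1 replicate 4 (adjusted p = 0.0519). All 3 endoplasmic reticulum folding genes were lower in eds16-1, ATERDJ3B by −1.37 ± 0.20, CRT1b by −1.08 ± 0.17 and BZIP60 by −0.85 ± 0.16 (list adjusted p = 2.6e-05, and adjusted p = 0.0215 with an estimated correlation). AT5G52810 (−2.17 ± 0.23, adjusted p = 2.7e-09), GRX480 (−1.97 ± 0.25), UGT76B1 (−1.11 ± 0.22), SAG101 (−0.71 ± 0.23) and WRKY6 (−0.79 ± 0.17) were lower as well. WRKY53 and PUB24 (−1.42 ± 0.31) were the early pattern response genes that passed, 2 of 6, without a call for the list (adjusted p = 0.0685). GH3.3 and WES1 were lower by −0.90 ± 0.27 and −0.67 ± 0.23, and SBPASE was higher by 0.40 ± 0.11. Of 2637 calls 853 (32.4%) were higher and 1784 lower, and the share of higher calls was 45.0% after a second quantile normalization. The count was 1673 without Col-0 replicate 4 and 1568 with only the arrays of 5 dpi in the fit.

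At 7 dpi AT5G03350 was 113.5-fold lower in eds16-1 (−6.83 ± 0.78, n = 4, adjusted p = 7.1e-09), at a mean level of 6.08 ± 0.81 against 12.90 ± 0.09 (SD). AT3G28510, an AAA-type ATPase, was 13.3-fold lower (adjusted p = 6.5e-18), AT3G48080 12.9-fold, GRX480 8.09-fold (adjusted p = 7.0e-13) and the lupeol synthase gene LUP5 8.04-fold (adjusted p = 1.2e-20). Further differences were −2.78 ± 0.20 for AT4G00700, −2.76 ± 0.51 for the receptor kinase gene AT1G35710, −2.73 ± 0.15 for AT3G07600, −2.68 ± 0.22 for cwINV6 and −2.67 ± 0.21 for the strictosidine synthase-like gene AT3G51440. The defensin gene PDF1.2 was 17.9-fold higher in eds16-1 (4.17 ± 1.05, adjusted p = 0.00449), at 12.30 ± 0.67 against 8.13 ± 0.92 (SD). PDF1.2b was 6.24-fold higher (adjusted p = 0.0252), and did not pass without Col-0 replicate 4 (0.132) or eds16-1 replicate 1 (0.0626), 2 (0.0639) or 3 (0.0632). The chitinase gene AT2G43590, the flavin monooxygenase gene AT5G61290, AT5G22460, the peptide gene AT4G37290 and the subtilase gene SBT1.3 were 3.81-fold, 3.80-fold, 3.63-fold, 3.62-fold and 3.46-fold higher (highest adjusted p 8.3e-05). AT1G65900 and AT4G24350 were 3.26-fold and 3.22-fold higher, and AT1G29660, a GDSL lipase, 2.92-fold (adjusted p = 0.0147, or 0.108 without Col-0 replicate 1).

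UGT76B1 was lower in eds16-1 by −2.12 ± 0.22 (adjusted p = 3.1e-10) and AT5G52810 by −1.95 ± 0.23 (adjusted p = 1.8e-08). UGT76B1 was 1 of 3 genes of salicylic acid turnover, and that list did not pass (adjusted p = 0.0939). WRKY53 (−2.38 ± 0.39) and PUB24 (−1.27 ± 0.31) were also lower. ATERDJ3B (−1.25 ± 0.20) and CRT1b (−0.85 ± 0.17) were lower, while BZIP60 stood at −0.09 (list adjusted p = 0.00808, and adjusted p = 0.241 with an estimated correlation). Of the Calvin cycle genes SBPASE (0.63 ± 0.11) and PRK (0.37 ± 0.08) were higher in eds16-1 (list adjusted p = 0.00808, and adjusted p = 0.241 with an estimated correlation). COR15A and COR15B were higher by 1.21 ± 0.40 and 1.28 ± 0.40, each call ending without any of 5 of the 8 arrays, and their list did not pass (adjusted p = 0.0939). There were 2537 calls, 1227 higher and 1310 lower, and 478 of at least 1, of which 380 were lower. Among all 13356 named genes, called or not, 1885 had values that did not overlap, where chance gives 2.86%. The 5 dpi and 7 dpi differences shared 994 lower features (103.5 expected) and 511 higher ones (46.3 expected). Outside the rule for named genes, and chosen after their values were seen, the probe sets 266385_at and 247573_at differed by −6.83 ± 0.55 and 3.32 ± 0.86.

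In uninfected leaves of day 7 the ribonuclease gene TRZ1 was lower in eds16-1 by −0.91 ± 0.17 (n = 4, adjusted p = 0.0256) and AT4G34310 by −0.46 ± 0.09 (adjusted p = 0.0473), calls that ended without any of 4 and 7 of the 8 arrays. There were 10 calls, 9 of them lower, 18 with the replicate block, and 0 by limma with only these arrays in the fit, where AT4G34310 and TRZ1 had an adjusted p of 1. Without Col-0 replicates 1, 2, 3 and 4 the count was 67, 1, 1 and 60, and without eds16-1 replicates 1, 2 and 3 it was 4, 2 and 1. A replicate block within each condition, an alternative chosen after seeing the data, raised the counts of genotype differences to 311 at 0 h, 88 at 6 hpi, 245 at 3 dpi, 4757 at 5 dpi, 4298 at 7 dpi and 200 in the uninfected leaves of day 7.

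**Figure D2:**
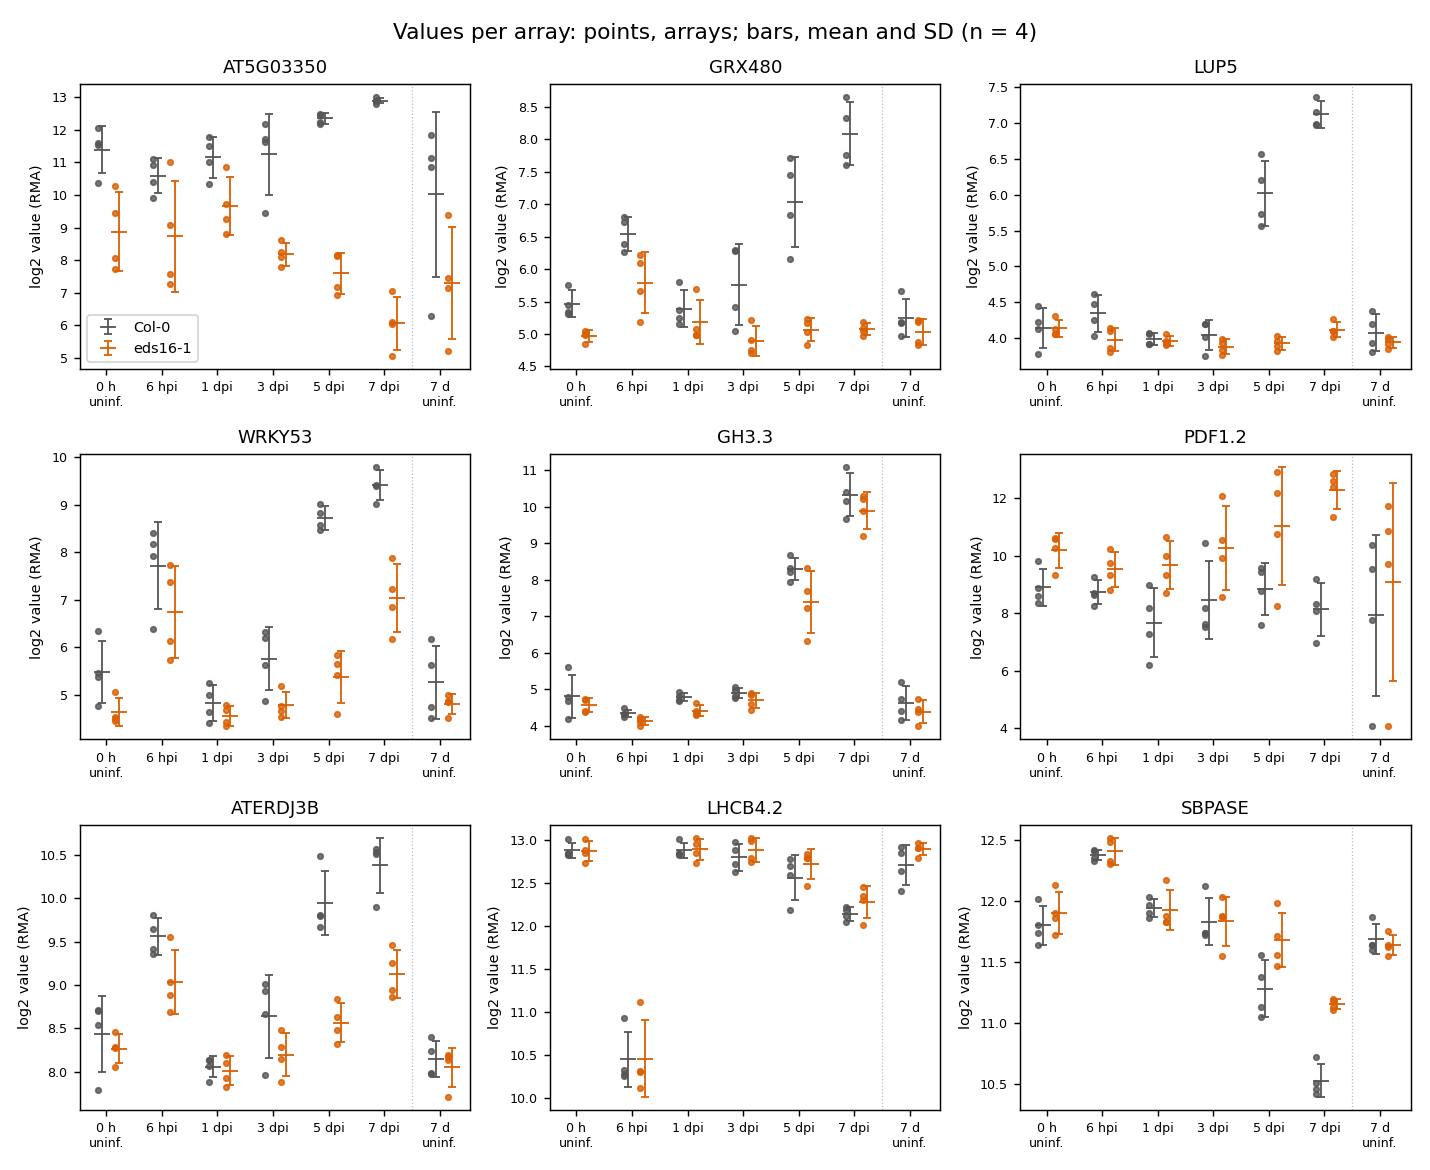
Log2 expression value (y axis, RMA) of AT5G03350, GRX480, LUP5, WRKY53, GH3.3, PDF1.2, ATERDJ3B, LHCB4.2 and SBPASE against time (x axis), with the uninfected leaves of day 7 to the right of the dotted line. Points are arrays and bars the mean and SD of 4 arrays, Col-0 in grey and eds16-1 in orange; at 7 dpi GRX480 stands at 8.09 in Col-0 and 5.08 in eds16-1, while GH3.3 stands at 10.33 and 9.89.

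The interaction asks whether the response to the mildew itself differs between the genotypes, which separate counts of calls cannot show. A fold value here is the ratio of the fold changes of both genotypes, so a smaller response can also be an absent or opposite one. At 6 hpi 1 feature was called, AT3G61920, whose response was higher in eds16-1 by 0.81 ± 0.15 (n = 4 in each of 4 groups, adjusted p = 0.0327, and 0.0585 with the replicate block), a call that ended without any of 10 of the 16 arrays. At 1 and 3 dpi limma made 0 calls, with 251 and 263 features at an unadjusted p under 0.05.

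At 5 dpi the response of LUP5 was 4.25-fold smaller in eds16-1 than in Col-0 (−2.09 ± 0.20, n = 4 in each of 4 groups, adjusted p = 4.1e-09). That of AT4G00700 was 4.43-fold smaller (adjusted p = 3.6e-06), AT2G44240 4.29-fold (adjusted p = 1.3e-05), AT3G51440 4.12-fold (adjusted p = 1.6e-05), AT5G52740 3.94-fold (adjusted p = 0.000955) and AT4G39830 3.53-fold (adjusted p = 0.000883). These 6 kept their calls without any single array. WRKY53 differed by −2.49 ± 0.55 (adjusted p = 0.0132), or −2.25 without Col-0 0 h replicate 1 (adjusted p = 0.0554) and −2.23 without eds16-1 5 dpi replicate 4 (adjusted p = 0.0565). AT5G55420 (−2.35 ± 0.57), AT1G65690 (−2.24 ± 0.53) and AT4G29520 (−1.84 ± 0.43) lost their calls without any of 8, 7 and 7 of the 16 arrays. The increases were smaller: AT1G78995 (0.87 ± 0.21), AT1G27480 (0.83 ± 0.20), AT1G64355 (0.63 ± 0.15) and AT1G64680 (0.57 ± 0.14) lost their calls without any of 12, 6, 10 and 9 arrays. Endoplasmic reticulum folding genes rose less in eds16-1 in 2 of 3 cases, or 3 adjusted over the list alone, with ATERDJ3B at −1.21 ± 0.28 and CRT1b at −0.94 ± 0.24 (list adjusted p = 1.4e-05, and adjusted p = 0.0167 with an estimated correlation), although both gene calls ended without any of 5 and 11 of the 16 arrays. GRX480 (−1.48 ± 0.35, adjusted p = 0.0271) and AT5G52810 (−1.35 ± 0.33, adjusted p = 0.0331) also passed, and did not without any of 8 and 10 arrays. GH3.3 and WES1 did not pass, at −0.65 ± 0.39 (adjusted p = 0.807) and −0.38 ± 0.33 (adjusted p = 0.942).

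Of the 150 calls at 5 dpi 141 were lower and 9 higher, and 101 were of at least 1 in size. The count was 274 with the replicate block, 538 with a replicate block within each condition, 84 with only the 4 groups in the fit and 351 against the mean of both uninfected groups. It was 96 without Col-0 0 h replicate 1 or Col-0 5 dpi replicate 1, 256 without Col-0 5 dpi replicate 2, 84 without Col-0 5 dpi replicate 4, 93 without eds16-1 0 h replicate 4 and 99 without eds16-1 5 dpi replicate 2.

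At 7 dpi the response of AT3G28510 was 12.7-fold smaller in eds16-1 (−3.66 ± 0.31, n = 4 in each of 4 groups, adjusted p = 6.1e-12), LUP5 7.31-fold (adjusted p = 6.5e-14), GRX480 6.94-fold (adjusted p = 3.9e-07), AT3G07600 6.13-fold and AT2G44240 5.49-fold. AT3G29240, AT4G00700, the glycosyltransferase gene UGT73D1 and AT5G53110 differed by −2.27 ± 0.18, −2.15 ± 0.28, −2.14 ± 0.18 and −2.13 ± 0.23 (highest adjusted p 6.3e-07). AT5G03350 differed by −4.10 ± 1.10 (adjusted p = 0.0455), which ended without any of 11 of the 16 arrays and with a trended prior (adjusted p = 0.0557). In uninfected Col-0 of day 7 its replicate 4 stood at 6.29, against 11.83, 11.14 and 10.85, which enlarges the difference. In uninfected eds16-1 of day 7 replicate 4 stood at 5.22, against 9.40, 7.14 and 7.46, which lessens it. Responses higher in eds16-1 were those of TBL38 (1.78 ± 0.41, adjusted p = 0.0121), AT4G37290 (1.65 ± 0.27), AT5G61290 (1.55 ± 0.30), the subtilase gene AT5G45650 (1.495 ± 0.33), AT3G57950 (1.36 ± 0.20), AT4G12830 (1.16 ± 0.24), AT3G26470 (1.14 ± 0.20) and the plastid chaperonin gene Cpn60beta4 (1.08 ± 0.24). SBT1.3 (1.62 ± 0.38, adjusted p = 0.0154) had an adjusted p of 0.0574 without replicate 1 of either Col-0 group of day 7, and AT2G43535 (1.16 ± 0.30) lost its call without any of 8 arrays. With only the 4 groups in the fit TBL38, AT5G61290, AT4G12830, AT3G26470, SBT1.3, AT2G43535 and AT5G03350 had an adjusted p of 0.349, 0.167, 0.111, 0.114, 0.124, 0.344 and 0.316.

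The response of UGT76B1, which was not called in eds16-1, was lower there at 7 dpi by −2.07 ± 0.30 (adjusted p = 1.2e-05). It was 1 of 3 genes of salicylic acid turnover (list adjusted p = 0.0417 with a median of −0.04, adjusted p = 0.175 with an estimated correlation, and 0.106 with the replicate block). AT5G52810 differed by −1.26 ± 0.33 (adjusted p = 0.0344), a call that ended without any of 12 of the 16 arrays and with only the 4 groups in the fit (adjusted p = 0.0986). SBPASE (0.68 ± 0.15, adjusted p = 0.00925) and PRK (0.44 ± 0.11, adjusted p = 0.0265, lost without any of 5 of the 16 arrays) fell less in eds16-1 (list adjusted p = 0.000104, and adjusted p = 0.0695 with an estimated correlation). ATERDJ3B differed by −1.16 ± 0.28 (adjusted p = 0.0223, lost without any of 7 arrays), 1 of 3 genes of its list or 2 adjusted over the list alone (list adjusted p = 0.0203, and adjusted p = 0.246 with an estimated correlation). WRKY53 (−1.93 ± 0.55, adjusted p = 0.071), PDF1.2 (3.01 ± 1.49, adjusted p = 0.578) and PDF1.2b (1.78 ± 1.16, adjusted p = 0.833) did not pass, nor did WES1 (0.29) and GH3.3 (−0.20), each with an adjusted p of 1. There were 285 calls, 191 of them lower, and 151 of at least 1. The count was 512 with the replicate block, 1125 with a replicate block within each condition, 188 with the dimmest features left out, 152 with only the 4 groups in the fit and 552 against the mean of both uninfected groups.

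Leaves of day 7 and of 0 h from plants that were not inoculated differ in age. In Col-0 AT5G20790 rose by 3.78 ± 0.72 (n = 4, adjusted p = 0.00527), AT1G03020 by 1.79 ± 0.35 and TBL38 by 1.36 ± 0.29, while AT2G10940 fell by 3.65 ± 0.81 (adjusted p = 0.00983), the GDSL lipase gene AT4G18970 by 2.09 ± 0.45 and AT3G07010 by 1.89 ± 0.50. In eds16-1 HIS1-3, a drought-inducible linker histone, rose by 2.79 ± 0.57 (adjusted p = 0.012), AT1G64360 rose by 1.83 ± 0.42 and AT1G27200 rose too, while AT2G10940, AT4G18970 and AT1G09750 fell by 2.93 ± 0.81, 1.92 ± 0.45 and 1.86 ± 0.56. COR47 rose by 1.11 ± 0.27 and 1.42 ± 0.27 in Col-0 and eds16-1, and LTI30 by 1.72 ± 0.48 and 2.03 ± 0.48. These were 2 of 4 cold and abscisic acid genes in each genotype, and 4 in eds16-1 adjusted over the list alone (list adjusted p = 0.0092 and 0.000554, and adjusted p = 0.501 and 0.366 with an estimated correlation). None of the light reaction genes passed in Col-0, although the list did (adjusted p = 0.00901, and adjusted p = 0.501 with an estimated correlation).

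Each of these 12 gene calls, and those of COR47 and LTI30, ended without replicate 4 of the day 7 uninfected group of its genotype, which left 4 of 881 calls in Col-0 and 19 of 1027 in eds16-1. The calls were 414 higher and 467 lower in Col-0 (47.0% higher, or 36.9% after median centring) and 658 higher and 369 lower in eds16-1 (64.1%, or 50.6% after median centring and 48.8% after a second quantile normalization). With only the groups compared in the fit 0 were called by limma in Col-0, where 3945 features had an unadjusted p under 0.05 in the fit of all arrays. Without Col-0 0 h replicates 2, 3 and 4 the count was 126, 192 and 294, and without Col-0 day 7 replicates 1 and 3 it was 2572 and 174. Without eds16-1 0 h replicates 1, 2 and 3 it was 351, 79 and 468, and without eds16-1 day 7 replicate 1 it was 75. With the replicate block it was 1866 in Col-0 and 3239 in eds16-1, and with both day 7 groups reduced to numbers 1 to 3, chosen after seeing the data, 22 and 221. The genotypes shared 186 higher features and 182 lower ones.

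Of 91 list calls among 864 tests 8 held with an estimated correlation. They were the endoplasmic reticulum folding list in Col-0 at 5 dpi and in the genotype difference and interaction of that day, the light reactions in both genotypes at 6 hpi, the auxin list in eds16-1 at 5 dpi, and the glutamate receptor-like family in the genotype difference and interaction at 7 dpi. The lists of sugar transport (lowest adjusted p 0.354), phenylpropanoids (0.0616) and reference genes (0.488) had no call in any comparison.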

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

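Chosen only after the result was seen were the tests of the growth chamber, the hour of harvest and RNA quality at 6 hpi, and those of a deviating array and of the age of the control leaves at 5 dpi.

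The 6 hpi change in both genotypes stood out because it was large and then absent. The 3506 features called in Col-0 at 6 hpi had a median change of 0.64 in their own direction (0.59 in eds16-1), and at 1 dpi 0.0304 of it was left, which argues against a lasting effect of the separate growth chamber, although a brief one stays open. Lower RNA quality is argued against by 3′ minus 5′ differences from 0 h of 0.143 in Col-0 and −0.0138 in eds16-1 (exact permutation p = 0.314 and 0.914, n = 4 in each group). GI, the only clock gene found by name, changed by at least 2.96 in each genotype (−2.96 and −3.08), against 0.21 and 0.09 at 1 dpi. This would go with leaves taken at another hour of the day, although the hour of harvest is not known here. An early response to the mildew remains a hypothesis that cannot be told apart from such an hour, since no uninfected leaves of 6 h were analysed here.

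The second pattern was that 215 features were called in eds16-1 at 5 dpi and 3839 in Col-0. A single deviating eds16-1 array is argued against, since leaving out any 1 of its 4 infected arrays gave at most 292 calls. The age of the 0 h control leaves is argued against only as the whole cause, since the interaction at 5 dpi still had 174 calls against the day 7 uninfected leaves, but a part stays open, as with that control the counts were 1634 in eds16-1 and 3275 in Col-0, and with the mean control 638 and 4103. Among 4029 features called at 7 dpi in both genotypes in 1 direction, the median 5 dpi change in the 7 dpi direction was 0.237 in eds16-1 and 0.49 in Col-0. It was smaller in eds16-1 in 4 of 4 pairs of replicate numbers, but all pairs share the 0 h means of their genotypes and are not independent. At 7 dpi the medians of these features were 0.646 in eds16-1 and 0.81 in Col-0. A smaller or later change of the same genes in eds16-1 may thus account for part of the difference in counts, as a hypothesis found and tested on the same data.

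The third pattern was replicate 4 of the uninfected leaves of day 7, which stood apart from its group in both genotypes. Its deviations in Col-0 and eds16-1 correlated at 0.785 across features, which are not independent replicates, against −0.0563, 0.672 and 0.483 for numbers 1, 2 and 3. Another hour of harvest is argued against by GI, which deviated by 0.46 at most, against 2.96 at 6 hpi. Lower RNA quality remains possible, since its 3′ minus 5′ value was the highest of 4 in both groups, by 0.144 in Col-0 and 0.0303 in eds16-1. Chance gives this in a share of 0.0625 if the 2 groups are independent. Their correlated deviations leave that open, so the share may be larger. Mildew on these uninfected plants cannot be told apart from other sources: the deviation in the direction of the Col-0 change at 5 dpi was 0.0508 in eds16-1 and 0.0931 in Col-0, where the other arrays ranged from −0.24 to 0.14, and no other biological explanation was tested.

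Single arrays far from the other 3 of their group were looked for in 521 sets of a named gene in a group with Dixon's test, and 45 were found (8.64%), where chance gives about 1 in 20. In the uninfected leaves of day 7 of Col-0, replicate 4 stood apart for AT1G51090 (11.62, against a mean of 9.84 in the others), AT4G12980 (7.88, 9.08), COR47 (12.61, 11.31) and LTI30 (12.25, 9.63), replicate 1 for SBPASE (11.87, 11.63) and AT5G20790 (5.46, 9.26), and replicate 2 for AT5G53110 (5.58, 5.16). In those of eds16-1, replicate 4 stood apart for AT3G20820 (9.14, 9.67), AT4G34220 (7.17, 8.08), PSBY (12.54, 12.92), AT5G45650 (7.51, 8.50) and AT1G64360 (10.44, 9.44), replicate 3 for AT4G34310 (6.68, 6.87) and replicate 1 for ATERDJ3B (7.71, 8.16). In Col-0 at 7 dpi, replicate 1 stood apart for AT4G00700 (9.18, 9.50), ATERDJ3B (9.90, 10.54), AT3G57950 (4.05, 4.49) and AT5G45650 (8.49, 8.02), and replicate 4 for AT1G78410 (8.25, 8.81) and AT4G12980 (6.67, 5.97). In eds16-1 at 7 dpi, replicate 4 stood apart for PDF1.2b (10.97, 11.98), AT2G43535 (8.50, 7.29) and UGT73D1 (4.33, 3.98), replicate 3 for cwINV6 (5.12, 4.89) and AT3G26470 (7.09, 6.12), and replicate 2 for AT1G62510 (5.99, 5.40) and CML37 (3.84, 4.36). In Col-0 at 5 dpi, replicate 4 stood apart for ATERDJ3B (10.49, 9.76) and AT2G31790 (8.83, 8.38), replicate 3 for WES1 (8.57, 8.02) and replicate 2 for AT3G51440 (6.44, 7.48). In eds16-1 at 5 dpi, replicate 1 stood apart for AT5G13140 (6.56, 7.57) and replicate 3 for AT4G39830 (4.87, 4.60). At 6 hpi, Col-0 replicate 2 stood apart for LHCB4.2 (10.93, 10.29), Col-0 replicate 1 for STZ (6.70, 9.34) and eds16-1 replicate 1 for WRKY22 (4.65, 5.24). At 0 h, Col-0 replicate 1 stood apart for LHCB4.2 (13.01, 12.83), PSBW (12.83, 12.65), AT1G13650 (9.18, 6.53) and TBL38 (5.67, 5.47), eds16-1 replicate 1 for AT1G20030 (8.18, 8.62) and AT5G62360 (9.64, 11.21), eds16-1 replicate 4 for STZ (8.07, 5.81) and WRKY53 (5.07, 4.49), and eds16-1 replicate 2 for AT2G44240 (4.66, 3.94).

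Among 70 sets of a quality measure in a group, 8 held such an array. They were the median of eds16-1 day 7 uninfected replicate 3 (5.876, against 5.833 in the others), the interquartile range of Col-0 3 dpi replicate 3 (3.472, 3.299), and the 3′ minus 5′ value of Col-0 6 hpi replicate 1 (1.604, 1.152) and Col-0 1 dpi replicate 3 (1.18, 1.03). The interquartile range of relative log expression was 0.298 in Col-0 0 h replicate 1 (0.203 in the others), 0.172 in Col-0 3 dpi replicate 4 (0.237) and 0.281 in eds16-1 6 hpi replicate 1 (0.342), and the mean correlation with its group was 0.9881 for Col-0 7 dpi replicate 4 (0.9896).

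Responses that differed between the genotypes by the interaction test numbered 1 at 6 hpi, 150 at 5 dpi and 285 at 7 dpi. The named one at 6 hpi was AT3G61920 (log2 difference of the responses 0.81). At 5 dpi they were WRKY53 (−2.49), AT5G55420 (−2.35), AT1G65690 (−2.24), AT4G00700 (−2.15), AT2G44240 (−2.10), LUP5 (−2.09), AT3G51440 (−2.04), AT5G52740 (−1.98), AT4G29520 (−1.84), AT4G39830 (−1.82), GRX480 (−1.48), AT5G52810 (−1.35), ATERDJ3B (−1.21), CRT1b (−0.94), AT1G64680 (0.57), AT1G64355 (0.63), AT1G27480 (0.83) and AT1G78995 (0.87). At 7 dpi they were AT5G03350 (−4.10), AT3G28510 (−3.66), LUP5 (−2.87), GRX480 (−2.80), AT3G07600 (−2.62), AT2G44240 (−2.46), AT3G29240 (−2.27), AT4G00700 (−2.15), UGT73D1 (−2.14), AT5G53110 (−2.13), UGT76B1 (−2.07), AT5G52810 (−1.26), ATERDJ3B (−1.16), PRK (0.44), SBPASE (0.68), Cpn60beta4 (1.08), AT3G26470 (1.14), AT2G43535 (1.16), AT4G12830 (1.16), AT3G57950 (1.36), AT5G45650 (1.495), AT5G61290 (1.55), SBT1.3 (1.62), AT4G37290 (1.65) and TBL38 (1.78).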

How the results depend on the processing

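The 2 settings not planned, and so tests chosen after the result was seen, were the replicate block within each condition and the day 7 uninfected groups reduced to numbers 1 to 3. Of 253 results for named genes 249 passed the threshold, and 129 of these passed it in every setting with a value. The 4 of these that reversed did so against the day 7 uninfected leaves: AT1G09750 and AT2G10940 in Col-0 at 5 dpi (0.29 and 1.11), and AT1G10640 and AT5G45670 in eds16-1 at 3 dpi (0.01 and 0.11). PDF1.2 and PDF1.2b in Col-0 at 7 dpi, which did not pass, stood at −1.09 and −0.20 with the reduced groups, and PDF1.2 at −0.28 with the mean control; leave-one-out values ran from −1.09 to 1.04 and from −0.20 to 1.23. Beside the reversed ones, results that kept their direction and no longer passed were 15 of 72 with the day 7 control, 10 of 184 with the mean control, 60 of 253 with only the groups compared, 51 of 253 at a log2 change of at least 1, 5 with the trended prior, 3 and 4 after median centring and quantile normalization, 1 with the replicate block, 25 of 130 with the reduced groups, 1 of 99 with the block within each condition (1 other newly passed), and 0 with all probe sets or the filter. Leaving out arrays was tried 3404 times over these results, a result counting once for each array or number left out, and 612 times the result no longer passed. By result, 78 of 249 lost the call without some single array. Signal over background was not given, so dim features cannot be told from absent ones here. Unless the setting itself shows it (fewer arrays, fewer features, a stricter threshold), the cause was not tested.

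With the replicate block the calls were 14, 35 and 18 for the genotype difference at 6 hpi, 3 dpi and uninfected day 7, 1 for Col-0 at 1 dpi, 447 for eds16-1 at 5 dpi, 0, 274 and 512 for the interaction at 6 hpi (limma, 350 at an unadjusted p under 0.05 without the block), 5 and 7 dpi, and 1866 and 3239 for the uninfected change in Col-0 and eds16-1. Of 40 calls of fixed lists 35 stayed with the block. The other 5 moved to an adjusted p of 0.0549 (early pattern, eds16-1 at 7 dpi), 0.0677 (early pattern, eds16-1 at 5 dpi), 0.0894 (early pattern, genotype difference at 6 hpi), 0.0517 (Calvin cycle, Col-0 at 5 dpi) and 0.106 (salicylic acid turnover, interaction at 7 dpi). AT3G61920 in the interaction at 6 hpi was the 1 named gene whose call the block ended. The numbers paired the samples in the genotype comparisons other than uninfected day 7 and at 1 dpi. With the block within each condition the genotype differences gave 311 (0 h), 88 (6 hpi), 245 (3 dpi), 4757 (5 dpi), 4298 (7 dpi) and 200 (uninfected day 7), and the interactions 0 (6 hpi), 538 (5 dpi) and 1125 (7 dpi).

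At 6 hpi the genotype difference gave 4 calls after median centring and 5 after quantile normalization. Leaving out the dimmest 40% gave 2 calls for eds16-1 at 3 dpi, 0 for the interaction at 6 hpi and 188 at 7 dpi. With only the groups compared in the fit, the genotype difference gave 0, 1, 1, 1568 and 0 calls at 6 hpi, 1, 3, 5 dpi and uninfected day 7, eds16-1 at 3 dpi 1, the interaction 0, 84 and 152 at 6 hpi, 5 and 7 dpi, and the uninfected change in Col-0 0. The trended prior gave 0 for the interaction at 6 hpi. At a log2 change of at least 1 the genotype difference kept 3, 1, 532 and 478 at 6 hpi, 1, 5 and 7 dpi, Col-0 863, 731 and 1641 and eds16-1 808, 99 and 1057 at 6 hpi, 5 and 7 dpi, the interaction 0 and 151 at 6 hpi and 7 dpi, and the uninfected changes 163 and 138.

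Against the day 7 uninfected leaves the counts were 1125 and 7 for Col-0 at 1 and 3 dpi, and 5748, 3 and 1634 for eds16-1 at 6 hpi, 3 and 5 dpi. Against the mean of both uninfected groups they were 5205, 3 and 638 for eds16-1, and 2, 351 and 552 for the interaction at 6 hpi, 5 and 7 dpi. With the reduced groups the uninfected changes were 22 in Col-0 and 221 in eds16-1.

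With an estimated correlation the adjusted p of lists rose in Col-0 to 0.0859 for early pattern genes at 6 hpi, 0.0749 for auxin at 5 dpi, and at 7 dpi to 0.145 (Calvin cycle), 0.0792 (auxin, calcium and endoplasmic reticulum each), 0.413 (cold), 0.172 (early pattern) and 0.405 (light reactions). In eds16-1 it rose to 0.0897 (early pattern) at 6 hpi, and at 7 dpi to 0.0519 (auxin), 0.0531 (calcium and endoplasmic reticulum each), 0.365 (early pattern) and 0.413 (light reactions). For the genotype difference at 7 dpi it was 0.241 (Calvin cycle and endoplasmic reticulum each), for the interaction at 7 dpi 0.0695 (Calvin cycle), 0.246 (endoplasmic reticulum) and 0.175 (salicylic acid turnover), and for the cold list in uninfected leaves 0.501 in Col-0 and 0.366 in eds16-1.

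Leaving out 1 array or 1 number at a time, the lowest and highest counts of the genotype difference were 1 and 73 at 0 h, 4 and 21 at 6 hpi, 0 and 2 at 1 dpi, 1 and 278 at 3 dpi, 1127 and 3008 at 5 dpi, 1537 and 2480 at 7 dpi, and 1 and 101 in uninfected leaves of day 7. For Col-0 they were 2139 and 3442 at 6 hpi, 0 and 0 at 1 dpi, 0 and 29 at 3 dpi, 2172 and 4166 at 5 dpi and 5443 and 6494 at 7 dpi, and for eds16-1 they were 2008 and 3559, 0 and 0, 0 and 9, 51 and 292, and 2798 and 4561. For the interaction they were 0 and 1 at 6 hpi, 0 and 0 at 1 and 3 dpi, 28 and 256 at 5 dpi, and 110 and 334 at 7 dpi, and for the uninfected change 0 and 2869 in Col-0 and 0 and 1205 in eds16-1. The lowest counts that arose without a whole number were 1127, 2172 and 28 (replicate 4), 1537, 5443, 2008 and 110 (replicate 2), 2139, 51 and 2798 (replicate 3), and the 0 of the uninfected change in Col-0 (replicate 2 or 3) and in eds16-1 (replicate 3), by limma with 3355, 2785 and 4228 features at an unadjusted p under 0.05.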

Other observations

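In this part the families were formed by symbol after the annotation was opened and before any comparison was computed, and the share over all splits was fixed before its result. That is not claimed for the counts of splits by same-numbered pairs, which rest on a pairing found in the data. Nor is it claimed for those by infected arrays kept together. Glutamate receptor-like channel genes changed with infection and genotype at 7 dpi. In Col-0 5 of 8 rose and 2 fell, or 3 adjusted over the list alone (median log2 change 1.00, list adjusted p = 0.00658, and adjusted p = 0.0792 with an estimated correlation). Compared with Col-0, 5 of 8 were lower in eds16-1 (median −0.44, list adjusted p = 0.000288, and adjusted p = 0.0162 with an estimated correlation). The interaction called 1 of 8, or 3 adjusted over the list alone (list adjusted p = 0.000104, and adjusted p = 0.0132 with an estimated correlation). At 5 dpi 3 of 8 were lower and 1 higher in eds16-1 (list adjusted p = 0.0457, adjusted p = 0.319 with an estimated correlation, and 0.0903 with the replicate block). Among calmodulin-like genes 4 of 7 rose in Col-0 at 7 dpi (list adjusted p = 0.0197, and adjusted p = 0.172 with an estimated correlation).

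In Col-0 at 5 dpi some members of the following 4 families fell, and none of their list calls held with an estimated correlation. TRICHOME BIREFRINGENCE-LIKE genes fell in 6 of 22 cases, or 7 adjusted over the list alone (list adjusted p = 0.0248, and adjusted p = 0.213 with an estimated correlation), and IQ-domain genes in 4 of 15, or 5 adjusted over the list alone (list adjusted p = 0.0136, and adjusted p = 0.212 with an estimated correlation). Expansins fell in 3 of 18 cases (list adjusted p = 0.0163, and adjusted p = 0.213 with an estimated correlation) and RALF-like peptide genes in 3 of 11 (list adjusted p = 0.0177, and adjusted p = 0.138 with an estimated correlation). These changes are against 0 h leaves, and in uninfected Col-0 leaves from 0 h to day 7 the expansin, RALF-like and IQ-domain lists were lower too (medians −0.25, −0.19 and −0.19, list adjusted p = 0.00557 each, and adjusted p = 0.280, 0.0646 and 0.280 with an estimated correlation), so the part due to infection is not separated. Tau glutathione transferases fell in 4 of 11 cases in Col-0 at 5 dpi (list adjusted p = 0.0231, and adjusted p = 0.166 with an estimated correlation) and in 5 of 11 in eds16-1 at 7 dpi (list adjusted p = 0.00674, and adjusted p = 0.0531 with an estimated correlation). Of 69 plastid-encoded genes 15 fell in eds16-1 at 7 dpi, or 17 adjusted over the list alone (median −0.60, list adjusted p = 1.2e-05, and adjusted p = 0.518 with an estimated correlation). In uninfected eds16-1 leaves 2 of 9 ATG8 autophagy genes rose by day 7, or 7 adjusted over the list alone (list adjusted p = 0.000549, and adjusted p = 0.366 with an estimated correlation). In uninfected Col-0 leaves that list passed as well, with 3 of 9 adjusted over the list alone (list adjusted p = 0.00897, and adjusted p = 0.604 with an estimated correlation). Without day 7 uninfected replicate 4 the calls of all features in these comparisons went from 1027 to 19 in eds16-1 and from 881 to 4 in Col-0. Of the 25 families 12 had no call in any comparison.

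Each count of calls was set against other splits of the same arrays into groups of the same sizes, 35 splits for comparisons of 2 groups and 100 drawn ones for interactions, the real split included. Shares over all splits take the arrays as independent and are not adjusted for the number of comparisons, so a small share does not exclude chance. Over all 35 splits only 1, the real one, gave as many calls in some comparisons, a share of 0.0286. This held for the genotype difference at 0 h (30 calls, highest other split 4), 1 dpi (2, highest other 0), 5 dpi (2637, 1930) and 7 dpi (2537, 278), for Col-0 at 6 hpi (3506, 820), 5 dpi (3839, 797) and 7 dpi (6741, 2450), for eds16-1 at 6 hpi (3395, 973), 3 dpi (6, 0), 5 dpi (215, 19) and 7 dpi (4948, 800), and for the uninfected change in eds16-1 (1027, 1). For the interaction at 5 dpi 3 of 100 splits gave as many (150, 558), a share under 0.05 over the splits drawn. The numbers pair the 2 genotypes at 0 h and at 5 dpi, though. Of the 6 drawn splits that part every pair 2 gave as many (highest other 303), too few to exclude chance with the pairing kept. Each of the 3 as large kept at least 3 of the 4 infected arrays of a genotype together, as did 60 of the 100. Such splits can keep the genotype difference of the infected leaves, so the share does not decide on chance.

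A share of at least 0.05 of the splits gave as many calls for the genotype difference at 6 hpi (12 of 35 splits, 8 calls, highest other 750), 3 dpi (3 of 35, 23, 732) and uninfected day 7 (9 of 35, 10, 926), and for the uninfected change in Col-0 (2 of 35, 881, 2317). The same held for the interaction at 7 dpi (8 of 100, 285, 2218) and 6 hpi (31 of 100, 1, 132). Splits for interactions regroup infected and uninfected arrays separately. A drawn split can thus keep the real genotype difference of the infected leaves, so these 2 shares do not decide on chance. In Col-0 at 1 and 3 dpi and in eds16-1 at 1 dpi limma made 0 calls (306, 766 and 367 features at an unadjusted p under 0.05), so 35 of 35 splits had to give as many, with highest others of 0, 70 and 0. For the interaction at 1 and 3 dpi limma also made 0 calls (251 and 263 features at an unadjusted p under 0.05), so 100 of 100 splits had to, with highest others of 10 and 1275. These 5 shares test nothing. Splits with several times the real count point to a structure of the samples. At 6 hpi and 3 dpi the highest other split set replicates 1 and 4 of both genotypes against replicates 2 and 3, and with the replicate block the real counts were 14 and 35. Among the 8 splits that part every same-numbered pair, the real one gave the most calls for the genotype difference at 0 h (highest other 0), 6 hpi (1), 1 dpi (0), 3 dpi (0), 5 dpi (178) and 7 dpi (66), and the others keep some pair together. With the pairing kept, 8 splits are too few for a share under 0.05. In the interaction at 7 dpi each of the 8 splits with as many calls kept at least 3 of the 4 infected arrays of a genotype together, as did 54 of the 100 drawn. Splits of this kind can keep the genotype difference of 7 dpi and are not free of a real difference.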
